A study of Mus musculus with 78 samples.

How the data were processed

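Bulk RNA sequencing of C57BL/6 mice was analysed in 78 libraries from the cecum, the colon, the hippocampus, the hypothalamus and peripheral blood mononuclear cells (PBMC). By their labels, mice were 8 weeks or 18 months old. They were kept either on a cycle of 12 h of light and 12 h of darkness (CON) or under circadian rhythm disruption (CRD). Per the labels' protocols, CRD mice had their light and dark phases inverted every 3 days for 4 weeks, then 48 h of light alternating with 48 h of darkness for 3 weeks, and then constant light for 1 week. As these stages lasted 4, 3 and 1 weeks, the label of 8 weeks cannot be taken as the age of CRD mice at tissue collection. Ages given below are those of the labels. Both schedules gave free access to food. RNA was extracted with Trizol, mRNA was selected with oligo(dT) beads, and cDNA was primed with random hexamers, per the labels' protocols. The hour of tissue collection, the sex of the animals and the sequencing batches were not given in the sources used here.

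The authors deposited 1 table of FPKM values (fragments mapped to a gene, scaled to its length and to the mapped total), with 20673 genes and 2 decimals. Per the submitters' processing notes, the tools were HISAT2, Bowtie2, RSEM and DESeq2 and the genome build was GRCm38; versions and settings were not given in the sources used here. FPKM holds no read counts, so the absolute depth of a library is unknown and no counting interval can be given. The steps between low values of 365 genes, 36 to 84 of them per library, gave the relative depth of the libraries, which ran from 0.837 to 1.084. Steps far from the median of a gene were left out. A library of very different depth could thus hardly stand out, and the narrow range does not show equal depth. The sum of FPKM over all genes ran from 430706 to 590745 in the 74 libraries of solid tissue and from 502827 to 960370 in PBMC. Of the genes, 19887 matched 1 gene of the GENCODE annotation of GRCm38, from which coordinates are given (counted from 1). In 3 cases a symbol stood on more than 1 row, 6 rows in all. The values do not state how reads shared by near-identical genes were divided, so members of families such as Ifit3 and Ifit3b, Hba-a1 and Hba-a2, and the Slfn and H2 genes are uncertain one by one.

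From there, values were taken as log2(FPKM + 1), and genes with a mean FPKM of at least 0.5 over the samples of a tissue were tested. In each solid tissue 1 linear model over the 4 groups (age by schedule) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance. The contrasts were CRD against CON at 18 months, CRD against CON at 8 weeks, the difference of these effects (18 months minus 8 weeks), and 18 months against 8 weeks in CON. PBMC, with 2 libraries per schedule at 18 months, were fitted alone. With 2 residual degrees of freedom there, limma took the variance of each gene from the fitted trend alone. PBMC errors and p-values thus do not measure the spread of a single gene between its libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of single genes are limma's. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes, and their errors are standard errors (SE) of the fit. Values in FPKM are means ± SD over libraries.

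The study's labels number replicates without stating that each number is a separate animal, so p-values measure the spread between these samples. In PBMC those of genes measure it only through the trend over genes. The numbers were not used as a block in the models described above.

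Gene lists (56, written before the data were examined) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison with at least 3 tested members, and again with a correlation estimated from the data. Members were also counted with p-values adjusted over the list alone. The lists most used are the clock genes, the interferon response, MHC class II, T and NK cells, and the microglial genes associated with disease and age. Genes were named by a rule fixed before the data were examined. It took the 5 largest rises and 5 largest falls among called genes with a mean of at least 1 FPKM in the higher group, leaving out predicted-gene symbols. It added called clock genes and up to 4 members, by smallest p, of each list that passed. With fewer than 3 calls, the 3 genes with the smallest p were given as values, and 10 clock genes were given in every solid tissue.

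Scores per library were the mean log2(FPKM + 1) of the 20 interferon genes, and a clock index, the mean of 8 genes of the output arm (Dbp, Tef, Hlf, Nr1d1, Nr1d2, Ciart, Per3, Bhlhe41) minus the mean of 5 genes of the Arntl arm (Arntl, Npas2, Clock, Cry1, Nfil3). The clock index and the tests on it were chosen after the fits had been seen, and the Arntl arm was shortened by 1 gene after results of the index had been seen. Scores were compared with two-sided exact permutation tests of the difference of means in scipy 1.17.1 under Python 3.11.15. Correlations across samples had 100000 permutations within groups. The differences of CRD effects between tissues were tested per clock gene with an F test of limma over all solid tissues, with tissues taken as independent samples.

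Alternatives were a pseudocount of 0.1, no filter or a minimum of 2 FPKM, median-of-ratios scaling, quantile normalization, a fit of the 2 compared groups alone, a replicate block, and each library left out in turn. Added after the data were examined were fits without hippocampus libraries with Ttr under 100 FPKM, PBMC values rescaled without globin genes, and the replicate number taken as the animal in the tests between tissues. For each contrast up to 100 other splits of the samples were fitted. The models were tested on simulated data with 100 genes changed by 1 log2 unit and 100 by 0.5. In the solid tissues 66% (cecum difference between ages) to 97% (hippocampus at 8 weeks and hypothalamus at 18 months) of the first were recovered, and 11% (colon difference between ages) to 86% (hypothalamus at 8 weeks) of the second. None had the wrong sign, and in PBMC 0% of either were recovered. Changes of 0.5, the size of many brain clock effects, can therefore be missed. The simulated noise was normal, independent between genes and of the same SD in all groups. Weakly expressed genes were not among those changed. In the real data single libraries stood apart and spreads differed between groups, so fewer changes may be recovered there. Mice under time-restricted feeding and PBMC of 8-week-old mice were not analysed here.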

Results

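The transcriptomes of 5 tissues and cell populations were measured by RNA sequencing in mice kept on a regular light cycle (CON) or under circadian rhythm disruption (CRD). In the cecum there were 4 CON and 4 CRD libraries at 18 months and 5 and 5 at 8 weeks. In the colon there were 5 CON and 4 CRD libraries at 18 months and 4 CON and 5 CRD libraries at 8 weeks. The hippocampus and the hypothalamus each had 4 CON and 5 CRD libraries at 18 months and 5 and 5 at 8 weeks. PBMC had 2 CON and 2 CRD libraries, all at 18 months. Values were FPKM, so the depth of each library was unknown. Genes above 0 numbered 16960 to 17753 per library of solid tissue and 15425 to 16151 per PBMC library.

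The first question was what CRD changed in the gut of old mice. In the cecum at 18 months, 3 of the 4 genes called under CRD were clock genes. Nr1d2, a nuclear receptor that represses Arntl (chromosome 14, 18204054 to 18239127, GRCm38), fell from 26.8 ± 2.30 FPKM (SD, n = 4) in CON to 8.14 ± 1.92 (n = 4) in CRD, a log2 change of -1.62 ± 0.17 (SE, adjusted p = 0.000353). Ciart, a repressor of the CLOCK and ARNTL dimer (chromosome 3, 95878503 to 95882251), fell from 8.03 ± 1.08 FPKM to 1.04 ± 0.345 (log2 change -2.16 ± 0.34, adjusted p = 0.0201). Cry1, a repressor that peaks later in the cycle (chromosome 10, 85131700 to 85185064), rose from 7.19 ± 0.363 FPKM to 15.9 ± 1.39 (1.05 ± 0.15, adjusted p = 0.00983). The remaining called gene was Mier3, at -0.78 ± 0.10. Dbp, a clock output factor, stood at 48.1 ± 11.4 FPKM in CON and 5.64 ± 1.73 in CRD (-2.90 ± 0.53, adjusted p = 0.0867), and Per3 at -1.51 ± 0.29 had the same adjusted p. The other clock genes were not called: Nr1d1 -1.81 ± 0.49, Per1 -0.89 ± 0.22, Per2 -1.11 ± 0.36, Arntl 1.18 ± 0.27 and Clock -0.08 ± 0.14. The hour of collection was not given. For clock genes, here and in the other tissues, a shift of the clock in time (its phase) thus cannot be told apart from a change of level.

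As a group, the 22 clock genes fell in the cecum at 18 months by camera (adjusted p = 0.0135; adjusted p = 0.404 with an estimated correlation). Over all genes 1 member was called higher and 2 lower, and 4 higher and 12 lower when adjusted over the list alone. The 20 interferon response genes, which code for antiviral effectors, rose by 1.01 on average (camera adjusted p = 1.11e-21; adjusted p = 0.314 with an estimated correlation). None of them was called over all genes and 18 were higher when adjusted over the list alone, among them Isg15 at 1.68 and Ifi44 at 1.57. Antimicrobial peptide genes rose by 0.86 on average over 12 members (camera adjusted p = 9.84e-06; adjusted p = 0.352 with an estimated correlation). None was called over all genes and 5 were higher when adjusted over the list alone, with Reg3b, a secreted lectin of the gut epithelium, at 4.24 ± 5.07 FPKM in CON and 192 ± 212 in CRD. Without CRD replicate 5 the mean of the list was 0.43. In all, 4 of 13747 genes were called (1 higher, 3 lower) and 2236 had an unadjusted p under 0.05. The median log2 change of all genes was -0.10 and was moved to -0.01 by median-of-ratios scaling, which called 2 genes. Without CRD replicate 3 there were 12 calls and without CON replicate 1 or 2 there were 2.

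In the cecum at 8 weeks, Gzma, a protease of cytotoxic lymphocytes (chromosome 13, 113093825 to 113100981), rose from 11.7 ± 1.90 FPKM (SD, n = 5) in CON to 35.5 ± 11.2 (n = 5) in CRD. Its log2 change was 1.49 ± 0.19 (adjusted p = 0.00661), and it was the single gene called of 13747, with 709 at an unadjusted p under 0.05. The genes with the next smallest p were Ifi27l2a, an interferon-induced gene, at -2.15 ± 0.35 and Cd7, a T and NK cell marker, at 0.92 ± 0.15, each with an adjusted p of 0.0537. The interferon list fell by 0.88 on average (camera adjusted p = 2.70e-24; adjusted p = 0.339 with an estimated correlation), with 0 members called by limma over all genes and 10 lower when adjusted over the list alone. MHC class II genes, which present antigen, rose by 0.82 on average (camera adjusted p = 5.14e-09; adjusted p = 0.578 with an estimated correlation), with 0 of 8 called by limma over all genes and 7 higher when adjusted over the list alone (mean 0.54 without CON replicate 5). None of the 10 clock genes was called: Dbp had -1.06 ± 0.48, Nr1d1 -1.06 ± 0.44, Ciart -0.50 ± 0.30, Nr1d2 -0.40 ± 0.15, Per2 0.34 ± 0.32, Cry1 0.30 ± 0.13 and Arntl 0.29 ± 0.24. Clock at 0.11, Per3 at 0.07 and Per1 at 0.02 lay nearer to 0.

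The series also asks whether the response to CRD depends on age. In the cecum, the change under CRD was more positive at 18 months than at 8 weeks for the interferon-induced Ifi27l2a (difference 3.68 ± 0.52), Bst2, which tethers budding virions (2.50 ± 0.40), and Ifitm3, which blocks virus entry (2.18 ± 0.35). H2-Q10, a class I histocompatibility gene, differed by 1.67 ± 0.26, and Trp53inp1, a p53 target, by -1.21 ± 0.20. Ifi27l2a stood at 221 ± 188 FPKM in CON and 515 ± 88.8 in CRD at 18 months (n = 4 each), and at 733 ± 208 and 166 ± 48.3 at 8 weeks (n = 5 each). These 5 genes had adjusted p-values from 0.0249 to 0.0272, and 2143 had an unadjusted p under 0.05. The interferon list differed by 1.89 on average (camera adjusted p = 1.09e-33; adjusted p = 0.115 with an estimated correlation), with 2 members called and 19 when adjusted over the list alone. The count rested on single libraries: it was 0 in 7 of 18 fits without 1 library (18-month CON replicates 1 and 2, 18-month CRD replicates 1 and 5, 8-week CON replicates 2 and 4, 8-week CRD replicate 3) and 84 without 8-week CON replicate 1 (41 more positive, 43 more negative). The balance turned in 2 of the 18 fits, this one among them.

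In the colon at 18 months, Dbp (chromosome 7, 45705088 to 45710203) fell from 56.1 ± 19.0 FPKM (SD, n = 5) in CON to 7.84 ± 4.04 (n = 4) in CRD, a log2 change of -2.73 ± 0.49 (adjusted p = 0.0163). Cry1 rose from 7.62 ± 2.43 to 19.1 ± 2.62 FPKM (1.26 ± 0.22, adjusted p = 0.0125). Ciart at -1.88 ± 0.42 (adjusted p = 0.0528), Nr1d1 at -1.57 ± 0.47, Arntl at 1.52 ± 0.46 and Nr1d2 at -1.10 ± 0.29 were not called, nor were Per3 at -0.74, Per1 at -0.39, Clock at 0.31 and Per2 at 0.00. Interferon genes made up many of the rises. Slfn4 rose by 3.13 ± 0.61, Slfn2 by 2.14 ± 0.39, Oas2, an activator of RNase L, by 1.97 ± 0.34, and Isg15, a ubiquitin-like modifier, by 1.91 ± 0.27 (40.4 ± 12.5 FPKM in CON and 153 ± 37.8 in CRD). Ifi27l2a rose by 1.97 ± 0.27, from 148 ± 49.4 to 563 ± 110 FPKM. Nupr1, a stress-induced chromatin protein, fell from 494 ± 100.0 to 210 ± 39.4 FPKM (-1.23 ± 0.17), and Slc12a8, Cgref1 and B4galnt1 fell by 1.15, 1.15 and 1.13.

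Of the 20 interferon genes in the colon at 18 months, 13 rose over all genes and 19 when adjusted over the list alone, with a mean of 1.19 (camera adjusted p = 6.70e-35; adjusted p = 0.0384 with an estimated correlation). MHC class II genes fell by 0.69 on average (camera adjusted p = 0.000369; adjusted p = 0.657 with an estimated correlation), with 0 of 8 called by limma over all genes and 7 lower when adjusted over the list alone. T and NK cell markers fell by 0.68 on average (camera adjusted p = 0.000655; adjusted p = 0.707 with an estimated correlation), with 0 of 14 called by limma over all genes and 4 lower when adjusted over the list alone (mean -0.44 without CON replicate 4). Neutrophil markers rose by 1.45 on average, and by 1.26 without CRD replicate 3 (camera adjusted p = 0.0373 at the preset correlation). In all, 76 of 14072 genes were called (51 higher, 25 lower). The split was 78 higher and 13 lower under median-of-ratios scaling. The balance turned in 2 of 18 fits without 1 library, that without CRD replicate 1 with 468 calls (117 higher, 351 lower) and that without 8-week CRD replicate 5 with 154 (71 higher, 83 lower). Without CRD replicate 4 the count was 22 (20 higher, 2 lower), and it was 48 without CON replicate 5, a library with Y-linked transcripts.

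In the colon at 8 weeks, 2 of 14072 genes were called, both lower under CRD, and 974 had an unadjusted p under 0.05. Ifi27l2a (chromosome 12, 103442167 to 103443680) fell from 739 ± 259 FPKM (SD, n = 4) in CON to 171 ± 27.4 (n = 5) in CRD, a log2 change of -2.04 ± 0.27, and Ms4a4c, a gene of myeloid and lymphoid cells, fell by 1.57 (SE 0.22; adjusted p = 0.00842 for both). H2-Aa, a chain of MHC class II, stood at 284 ± 124 FPKM in CON and 766 ± 138 in CRD (1.52 ± 0.26, adjusted p = 0.0740). MHC class II genes rose by 1.00 on average (camera adjusted p = 1.74e-12; adjusted p = 0.209 with an estimated correlation), with 0 of 8 called by limma over all genes and 7 higher when adjusted over the list alone. T and NK cell markers rose by 0.94 (camera adjusted p = 6.64e-13; adjusted p = 0.304 with an estimated correlation), with 0 of 14 called by limma over all genes and 11 higher when adjusted over the list alone. The interferon list fell by 0.52 (camera adjusted p = 1.28e-17; adjusted p = 0.209 with an estimated correlation), with 1 member called and 8 when adjusted over the list alone. No clock gene was called, with Nr1d1 at -0.85, Ciart at -0.73, Dbp at -0.62, Cry1 at 0.57, Arntl at 0.48, Per2 at 0.47, Nr1d2 at -0.38, Per3 at 0.18, Per1 at -0.12 and Clock at 0.08. Both calls were lost without 8-week CON replicate 2, and without 8-week CON replicate 5 there were 7 (5 higher, 2 lower), where the balance turned.

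The effects of CRD on the colon differed between ages for 52 of 14072 genes, 44 with a more positive change at 18 months and 8 with a more negative one. Interferon genes led the first set: Ifi27l2a differed by 4.01 ± 0.38 (adjusted p = 7.69e-05), Ifit3 by 2.73 ± 0.41, Oas2 by 2.72 ± 0.48, Isg15 by 2.47 ± 0.38, Ifit3b by 2.44 ± 0.41, Xaf1 by 1.71 ± 0.24 and Oas1a by 1.29 ± 0.14. Of the 20 interferon genes, 13 were called and 18 when adjusted over the list alone (mean 1.70, camera adjusted p = 9.17e-56; adjusted p = 0.00473 with an estimated correlation). The second set held Ccl5, a chemokine of T cells (-3.55 ± 0.67), the lymphocyte genes Cd7 (-3.03 ± 0.60) and Cd3d (-1.73 ± 0.34), and the antigen presentation genes Cd74 (-2.55 ± 0.40), H2-Aa (-2.33 ± 0.36), H2-DMa (-2.11 ± 0.37) and H2-DMb1 (-2.07 ± 0.35). Of 8 MHC class II genes, 5 were called and 7 when adjusted over the list alone (mean -1.68, camera adjusted p = 1.19e-12; adjusted p = 0.108 with an estimated correlation). Of 14 T and NK cell markers, 1 was called and 13 when adjusted over the list alone (mean -1.62, camera adjusted p = 1.48e-13; adjusted p = 0.268 with an estimated correlation). The median difference of all genes was -0.10, and it was 0.03 under median-of-ratios scaling. Ifi27l2a was called at both ages, at 1.97 ± 0.27 and -2.04 ± 0.27, and no other gene was.

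**Figure D1:**
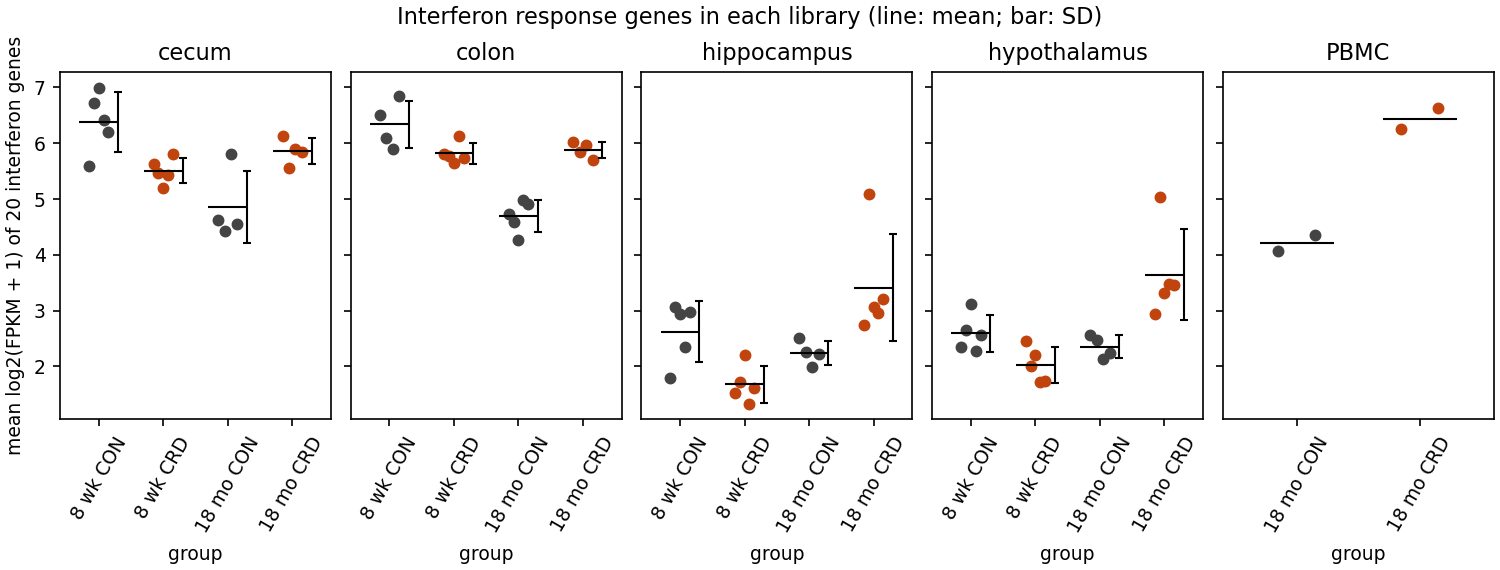
Mean log2(FPKM + 1) of 20 interferon response genes per library (points) in each tissue and group, with group means (lines) and SD (bars, groups of more than 2). At 18 months the CRD means lie above the CON means (for example 5.88 against 4.70 in the colon), and at 8 weeks they lie below (5.82 against 6.34).

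The score of the 20 interferon genes per library gave the same directions in each solid tissue. At 18 months CRD minus CON was 1.01 in the cecum (two-sided exact permutation p = 0.0571), and in the colon, hippocampus and hypothalamus it was 1.19, 1.17 and 1.29 (exact p = 0.0159 each, adjusted p = 0.0317 over 8 tests). At 8 weeks it was -0.88 in the cecum (exact p = 0.0238, adjusted p = 0.0381), -0.52 in the colon (0.0476, adjusted p = 0.0544), -0.94 in the hippocampus (0.0159, adjusted p = 0.0317) and -0.56 in the hypothalamus (exact p = 0.0318, adjusted p = 0.0423). In both brain regions 18-month CRD replicate 2 stood far above its group, at 5.09 in the hippocampus and 5.04 in the hypothalamus, and without it the rises were 0.75 and 0.95. Immune cell markers (T, NK and B cells and macrophages) had means of the other sign in the gut, -0.40 in both gut tissues at 18 months, 0.43 in the cecum at 8 weeks and 0.41 in the colon at 8 weeks (exact p = 0.0317 for the last, 0.190 to 0.314 for the others, adjusted p from 0.254 to 0.419). Neutrophil markers were not part of this set, and in the colon at 18 months they rose with the interferon genes, by 1.45 on average.

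In the hippocampus at 18 months limma called 0 of 14313 genes under CRD, and 749 had an unadjusted p under 0.05. The smallest p-values belonged to Epsti1, an interferon-responsive gene (0.57 ± 0.11), Gkn3 (-1.13 ± 0.23) and Rtp4, an interferon-induced chaperone, with 3.13 ± 0.343 FPKM (SD, n = 4) in CON and 14.5 ± 11.7 (n = 5) in CRD (1.67 ± 0.34), each at an adjusted p of 0.437. The interferon list rose by 1.17 on average (camera adjusted p = 4.19e-25; adjusted p = 0.442 with an estimated correlation), and 16 of 20 members were higher when adjusted over the list alone. Without CRD replicate 2, which stood apart, the rise was 0.75 (camera adjusted p = 5.87e-18). Clock genes were not called: Dbp had -0.68 ± 0.15 (76.8 ± 5.52 FPKM in CON, 47.4 ± 3.32 in CRD), Ciart -0.56 ± 0.14, Per2 -0.44 ± 0.17, Per3 -0.43 ± 0.17, Cry1 0.38 ± 0.11, Nr1d1 -0.33 ± 0.10, Per1 -0.32 ± 0.21, Nr1d2 -0.29 ± 0.13, Arntl 0.27 ± 0.15 and Clock -0.06 ± 0.10. The choroid plexus list, markers of the tissue that makes cerebrospinal fluid, fell by 1.57 on average (camera adjusted p = 7.31e-05; adjusted p = 0.675 with an estimated correlation). Of the hippocampus libraries 4, all CRD (18-month replicates 1 and 4, 8-week replicates 2 and 4), had 35.5 to 86.4 FPKM of Ttr, a choroid plexus transcript, against at least 3000 in each other hippocampus library. Without these 4 libraries, a fit chosen after the data were examined, Dbp was called at -0.65 ± 0.08 (adjusted p = 0.00506).

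In the hippocampus at 8 weeks limma also called 0 of 14313 genes, with 2948 at an unadjusted p under 0.05. Ifi27l2a stood at 27.2 ± 17.9 FPKM (SD, n = 5) in CON and 5.33 ± 3.33 (n = 5) in CRD (-2.06 ± 0.45), Eif2s3y at -0.60 ± 0.11 and Ebp, a sterol isomerase, at 0.36 ± 0.08, each with an adjusted p of 0.167. The interferon list fell by 0.94 (camera adjusted p = 3.25e-07; adjusted p = 0.706 with an estimated correlation), with 12 members lower when adjusted over the list alone. Clock genes were not called, with Nr1d2 at -0.48, Per2 at -0.45, Clock at -0.32, Per1 at -0.32, Ciart at -0.31, Per3 at -0.31, Nr1d1 at -0.27, Cry1 at 0.25, Dbp at -0.07 and Arntl at -0.05. Between ages the CRD effects differed for Ifi27l2a by 4.01 ± 0.65, Rtp4 by 2.91 ± 0.46 and Epsti1 by 0.91 ± 0.15 (adjusted p = 0.0309 each), the 3 genes called. The interferon list differed by 2.11 (camera adjusted p = 2.32e-47; adjusted p = 0.0599 with an estimated correlation), with 2 members called and 19 when adjusted over the list alone. The 3 calls were lost in 15 of 19 fits without 1 library, and were 9 without 18-month CRD replicate 2. They were also lost without the low-Ttr libraries, where the list differed by 2.39 (camera adjusted p = 2.36e-41).

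In the hypothalamus at 18 months 4 of 14437 genes were called, all higher under CRD and all induced by interferon. Ifi27l2a rose from 8.38 ± 2.49 FPKM (SD, n = 4) to 35.5 ± 14.2 (n = 5), a log2 change of 1.91 ± 0.31 (adjusted p = 0.0308), and Rtp4 from 3.38 ± 0.762 to 17.5 ± 12.9 FPKM (1.88 ± 0.31, adjusted p = 0.0310). Lgals3bp, a secreted glycoprotein, rose by 1.31 ± 0.21 and Ifi27 by 1.13 ± 0.18. The interferon list rose by 1.29 (camera adjusted p = 3.22e-23; adjusted p = 0.288 with an estimated correlation), with 2 members called and 19 when adjusted over the list alone, and 1746 genes had an unadjusted p under 0.05. Dbp was not called at -0.71 ± 0.14 (89.6 ± 7.29 FPKM in CON, 54.4 ± 6.64 in CRD), nor were Nr1d1 at -0.44, Ciart at -0.31, Nr1d2 at -0.30, Arntl at 0.21, Per3 at -0.12, Per2 at 0.10, Per1 at 0.04, Clock at -0.01 and Cry1 at -0.00. The 4 calls were lost in 5 of 19 fits without 1 library (18-month CON replicates 2, 3 and 4, 18-month CRD replicates 4 and 5), with no filter on low values and in a fit of these groups alone, and without 18-month CRD replicate 1 there were 18 (14 higher, 4 lower).

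In the hypothalamus at 8 weeks limma called 0 of 14437 genes, and 203 had an unadjusted p under 0.05. Ifi27 had -1.02 ± 0.17 (adjusted p = 0.0884), Lgals3bp -1.08 ± 0.20 (0.182) and Ifi27l2a -1.43 ± 0.29 (0.502). The interferon list fell by 0.56 (camera adjusted p = 2.43e-20; adjusted p = 0.154 with an estimated correlation), with 2 members lower when adjusted over the list alone. Clock genes stood at -0.40 (Nr1d1), -0.35 (Dbp), -0.26 (Ciart), -0.25 (Per1), 0.15 (Arntl), 0.11 (Per3), 0.06 (Clock and Cry1), -0.03 (Per2) and 0.00 (Nr1d2), none called. Between ages the CRD effects differed for 7 genes, all more positive at 18 months: Ifi27l2a by 3.34 ± 0.43, Rtp4 by 2.69 ± 0.43, Bst2 by 2.43 ± 0.44, Lgals3bp by 2.39 ± 0.29 and Ifi27 by 2.15 ± 0.24, with Irf9, a subunit of the interferon-activated transcription factor, at 1.76 ± 0.32 and Slfn2 at 1.46 ± 0.26, named after their values were seen. Of the 20 interferon genes 3 were called and 18 when adjusted over the list alone (mean 1.86, camera adjusted p = 1.84e-38; adjusted p = 0.113 with an estimated correlation). There were 3 calls without 18-month CON replicate 2 and 22 without 18-month CRD replicate 2.

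**Figure D2:**
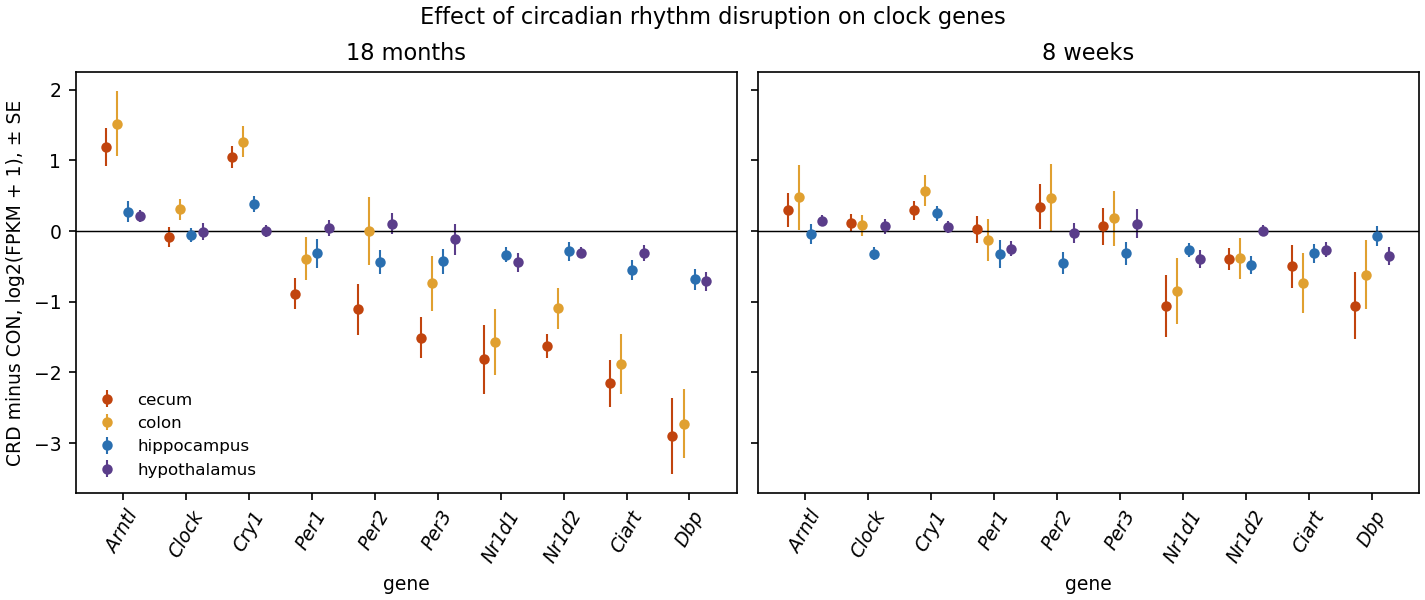
Log2 change under CRD (± SE) of 10 clock genes in 4 tissues at 18 months (left) and 8 weeks (right), on the log2(FPKM + 1) scale. At 18 months Dbp stands at -2.90 in the cecum and -2.73 in the colon, and at -0.68 and -0.71 in the hippocampus and hypothalamus.

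At 18 months the CRD effects on clock genes differed in size between tissues, at hours of collection that were not given. Differences of phase and of level therefore cannot be told apart. The F test took 1 spread per gene for all tissues. The SD of the clock index was 0.07 to 0.13 in the 18-month brain groups and 0.18 to 0.78 in the 18-month gut groups. In 8-week CRD it was 0.93 in the cecum and 1.06 in the colon. The differences between tissues were not tested between the 2 ages. At 18 months 14 of 22 clock genes had effects that differed between the 4 solid tissues when adjusted over the list alone, and at 8 weeks 0 of 22 did by limma's F test. Dbp (adjusted p = 5.11e-07), Cry1 (2.06e-06), Ciart and Nr1d1 (5.47e-05 each) had the smallest values at 18 months. The clock index, output genes minus the Arntl arm, had a CRD minus CON difference at 18 months of -2.53 in the cecum (two-sided exact permutation p = 0.0286, adjusted p = 0.0508). It was -2.27 in the colon, -0.51 in the hippocampus and -0.43 in the hypothalamus (exact p = 0.0159 each, adjusted p = 0.0423). At 8 weeks the difference was -0.70 in the cecum, -0.57 in the colon, -0.19 in the hippocampus and -0.21 in the hypothalamus (exact p from 0.0318 to 0.333, adjusted p from 0.0508 to 0.333). The list fell by camera in the hippocampus at 18 months (adjusted p = 0.0343; adjusted p = 0.675 with an estimated correlation; 0.344 without the low-Ttr libraries, where its mean was -0.07). It also fell in the hypothalamus at 18 months (mean -0.09, camera adjusted p = 0.0126, and 0.292 with an estimated correlation). At 8 weeks its mean there was -0.06 (camera adjusted p = 0.00295, and 0.154 with an estimated correlation). Without 8-week CRD replicate 5 that mean was -0.03 (camera adjusted p = 0.0414). For the difference between ages limma called 0 clock genes over all genes in each solid tissue. In the cecum 4 had a more positive and 8 a more negative change at 18 months when adjusted over the list alone, and the list mean was -0.54 (camera adjusted p = 0.0316; adjusted p = 0.590 with an estimated correlation). The smallest p was that of Nr1d2, at -1.23 ± 0.23 (adjusted p = 0.0625 over all genes). In the colon, hippocampus and hypothalamus 0 of 22 differed between ages by limma when adjusted over the list alone.

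Across all tested genes, the CRD effects at the 2 ages correlated (over genes, which are not independent replicates) with r = -0.212 in the cecum, -0.0243 in the colon, 0.478 in the hippocampus and -0.0145 in the hypothalamus. Of the splits of the samples, 20 of 35 in the cecum, and 97, 35 and 94 of 100 in the colon, hippocampus and hypothalamus, gave a correlation as far from 0, so none stood apart from regrouped samples.

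In PBMC at 18 months (n = 2 per schedule) interferon and neutrophil genes were higher under CRD. Errors and calls of single genes here rest on the variance trend over genes, not on the spread of each gene. Isg15 was at 20.6 and 15.7 FPKM in CON and at 701 and 244 in CRD. Isg15 rose by 4.45 ± 0.57, Slfn4 by 4.27 ± 0.56 and Ifit3 by 4.00 ± 0.55, and 10 of 20 interferon genes were called, 16 when adjusted over the list alone (mean 2.24, camera adjusted p = 6.13e-64; adjusted p = 0.134 with an estimated correlation). Of 11 neutrophil genes 9 rose, all 11 when adjusted over the list alone (camera adjusted p = 3.61e-48; adjusted p = 0.134 with an estimated correlation), among them S100a8 at 3.23 ± 0.60, S100a9 at 3.29 ± 0.61 and Retnlg at 3.44 ± 0.58. The cytokine gene Il1b rose by 2.53 ± 0.57 and Lcn2, an iron-binding protein of neutrophils, by 2.81 ± 0.57. Hpgd, which degrades prostaglandins, fell by 2.45, Fn1 by 2.25, Slc12a2 by 2.17, Mdm1 by 2.12 and Klra23, an NK cell receptor, by 1.99. All 9 erythrocyte genes rose (camera adjusted p = 1.97e-52, and 0.261 with an estimated correlation), with Hba-a2 at 3.93 ± 0.67. Globin transcripts took 5.6% of the FPKM sum of CRD replicate 2, 4.8% and 0.49% of CON replicates 1 and 2, and 41.0% of CRD replicate 1. Neutrophils and erythrocytes are not mononuclear cells, so their transcripts may reflect the cell content of the preparations. That content and a response to CRD cannot be told apart here. The mean of the erythrocyte list was 3.28, and 1.61 without CRD replicate 1. In all 133 of 11770 genes were called (110 higher, 23 lower) against a median of -0.49 for all genes. Median-of-ratios scaling moved that median to -0.01 and left 0 calls, rescaling without globins left 87. The balance turned without CRD replicate 2, with 5261 calls (550 higher, 4711 lower), and without CON replicate 2 there were 7 (3 higher, 4 lower). Such a fit leaves 1 library on a schedule, which is assumed to vary like the 2 of the other.

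The last comparison set 18-month against 8-week mice in CON. Y-linked transcripts separated the ages: Ddx3y was at 9.20 FPKM or more in 39 of 39 libraries at 8 weeks and at 0.06 or less in 38 of 39 libraries at 18 months. The exception, colon 18-month CON replicate 5, had 11.3 FPKM. Age was therefore confounded with sex in these libraries, and the comparisons of ages, the differences of CRD effects included, cannot separate the 2. The age comparison also shares its 18-month and 8-week CON libraries with the CRD effects at these ages. Interferon changes by age and under CRD are therefore not independent. At 18 months and 8 weeks the mean interferon scores were 4.85 and 6.39 in cecum CON, and 5.86 and 5.51 in cecum CRD. In the colon they were 4.70 and 6.34 in CON, and 5.88 and 5.82 in CRD. Hippocampus CON had 2.24 and 2.62 and CRD 3.41 and 1.68, hypothalamus CON 2.35 and 2.59 and CRD 3.65 and 2.03. In the gut the CRD means thus lay nearer to each other than the CON means, in the brain the reverse.

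**Figure D3:**
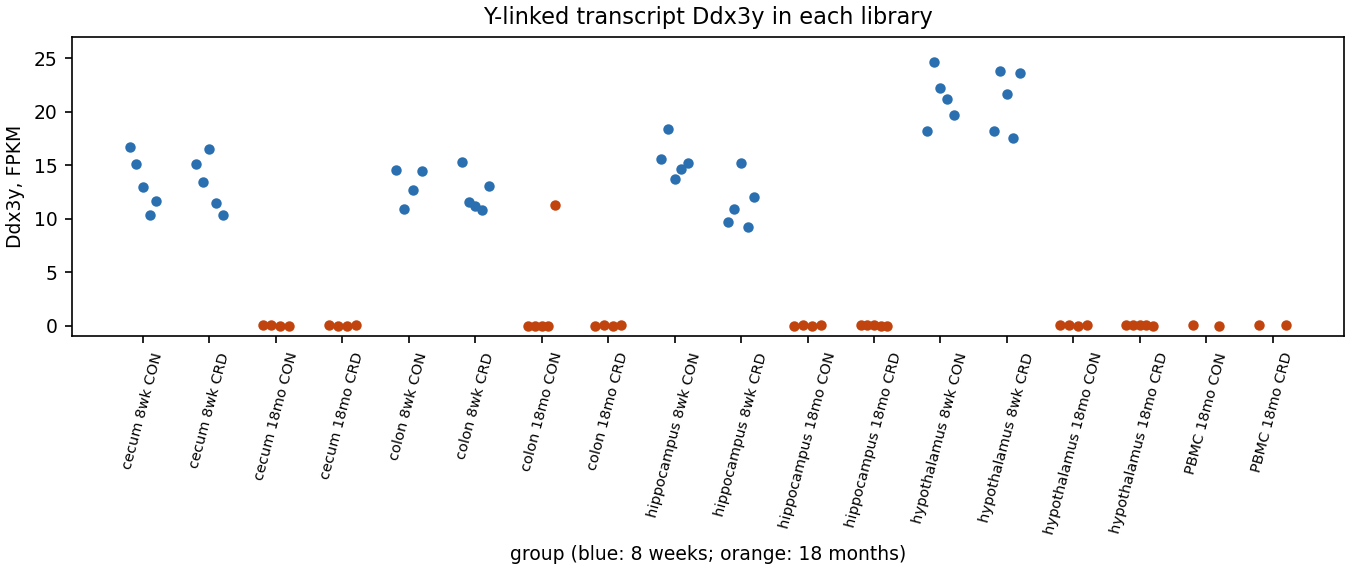
FPKM of the Y-linked transcript Ddx3y in each library, by tissue and group. Libraries at 8 weeks (blue) lie between 9.20 and 24.7, and those at 18 months (orange) at 0.06 or below except for 1 colon library at 11.3.

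In the cecum of CON mice 207 of 13747 genes were called for age (97 higher and 110 lower at 18 months). The interferon list was lower by 1.53 on average, with 19 of 20 members called and all 20 when adjusted over the list alone (camera adjusted p = 9.39e-38; adjusted p = 0.0376 with an estimated correlation). Ifi27l2a fell by 2.01 ± 0.37, the chemokine gene Cxcl10 by 2.25 ± 0.53 and the GTPase gene Iigp1 by 2.08 ± 0.34. The secreted lectins Reg3b (chromosome 6, 78370657 to 78373466) and Reg3g were lower, Reg3b with 4.24 ± 5.07 FPKM (SD, n = 4) at 18 months and 142 ± 53.6 (n = 5) at 8 weeks (-5.21 ± 1.02, adjusted p = 0.0187), and Reg3g at -3.33 ± 0.75. The granzymes Gzma and Gzmb fell by 1.05 and 1.62. Glycam1 rose by 2.96 ± 0.60, Cyp4b1, a monooxygenase, by 2.56 ± 0.55, Ceacam10 by 1.90 ± 0.32 and Gpam, an enzyme of triglyceride synthesis, by 1.48 ± 0.26, and Nr1d2 was the clock gene called, at 0.71 ± 0.16. The split was 60 higher and 118 lower under median-of-ratios scaling and 50 and 93 under quantile normalization. The count was 26 without 18-month CON replicate 1 (11 higher, 15 lower) and 315 without 8-week CON replicate 1 (162 higher, 153 lower). The balance turned in 6 of 18 fits without 1 library.

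In the colon of CON mice 138 of 14072 genes were called for age, 31 higher and 107 lower at 18 months. Of the 20 interferon genes 18 were lower over all genes and 20 when adjusted over the list alone (mean -1.64, camera adjusted p = 1.41e-58; adjusted p = 0.00372 with an estimated correlation). Isg15 fell by 2.48 ± 0.27, Ifi27l2a by 2.30 ± 0.27, Usp18, which removes ISG15, by 2.06 ± 0.21 and Bst2 by 1.73 ± 0.18. Slfn4 fell by 3.20 ± 0.61 and the chemokine genes Cxcl10 and Ccl2 by 2.10 and 1.04. Vsig2 rose by 1.77 ± 0.31, Pbld1 by 1.74 ± 0.35, Dio1, a thyroid hormone deiodinase, by 1.52 ± 0.35, Dmrta2 by 1.17 ± 0.26 and Tmem171 by 1.07 ± 0.22. The split was 19 higher and 142 lower under median-of-ratios scaling. The count was 71 without 8-week CON replicate 2 (5 higher, 66 lower) and 178 without 18-month CON replicate 5 (64 higher, 114 lower). The balance turned without 8-week CON replicate 5, with 255 calls (141 higher, 114 lower).

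In the brain of CON mice lists of microglial and complement genes were higher at 18 months. Erythrocyte genes were higher as well, by 0.91 on average in the hippocampus and 1.14 in the hypothalamus. Monocyte and macrophage genes were higher by 0.50 and 0.63. In the hippocampus C4b, a complement component (chromosome 17, 34728380 to 34743882), rose from 12.3 ± 2.06 FPKM (SD, n = 5) to 37.0 ± 7.68 (n = 4), a log2 change of 1.51 ± 0.16 (adjusted p = 2.55e-05), and Clec7a, a receptor of activated microglia (chromosome 6, 129461591 to 129472779), from 0.542 ± 0.197 to 3.41 ± 0.916 FPKM (adjusted p = 2.92e-05). Lyz2 rose by 1.78 ± 0.23, Klk6, a protease of oligodendrocytes, by 1.66 ± 0.30, Cst7 by 1.64 ± 0.18, C3 by 1.04 ± 0.15, Gpnmb by 0.93 ± 0.11 and Cd68 by 0.92 ± 0.11. Of 14 microglial genes associated with disease and age, 5 were called and 9 when adjusted over the list alone (mean 0.71, camera adjusted p = 2.50e-15; adjusted p = 0.00210 with an estimated correlation). Of 11 complement genes 2 were called and 7 when adjusted over the list alone (mean 0.61, camera adjusted p = 9.62e-09; adjusted p = 0.0152 with an estimated correlation). Of 67 called genes in 14313, 55 were higher and 12 lower. Among the lower ones were Igsf9b (-0.83 ± 0.17), an adhesion protein of inhibitory synapses, and the Y-linked Eif2s3y (-4.25 ± 0.12) and Ddx3y (-4.01 ± 0.11). The count was 25 without 18-month CON replicate 1 (19 higher, 6 lower) and 284 without 8-week CRD replicate 2 (151 higher, 133 lower). The balance turned without the low-Ttr libraries, with 997 calls (381 higher, 616 lower).

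**Figure D4:**
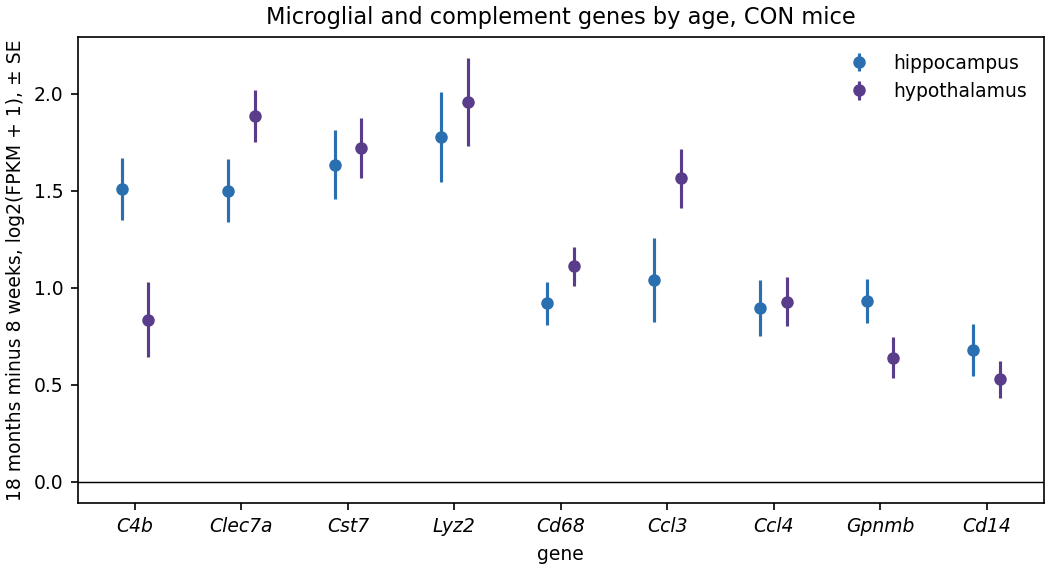
Log2 difference (± SE) between 18 months and 8 weeks in CON mice for 9 microglial and complement genes in the hippocampus and hypothalamus, on the log2(FPKM + 1) scale. Each lies above 0 in both regions, with Lyz2 at 1.78 and 1.96.

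In the hypothalamus of CON mice 1436 of 14437 genes were called for age, 539 higher and 897 lower at 18 months. Clec7a rose from 0.462 ± 0.304 FPKM (SD, n = 5) to 4.34 ± 0.490 (n = 4), a log2 change of 1.89 ± 0.13 (adjusted p = 3.69e-08), with Lyz2 at 1.96 ± 0.23, Cst7 at 1.72 ± 0.15, the chemokine gene Ccl3 at 1.56 ± 0.15, the lysosomal gene Cd68 at 1.11 ± 0.10, and C1qa, C1qb and C1qc, which start the classical complement pathway, at 0.83, 0.79 and 0.74. Of 14 microglial genes associated with disease and age, 11 were called and 12 when adjusted over the list alone (mean 0.83, camera adjusted p = 5.85e-19; adjusted p = 0.00234 with an estimated correlation). Of 9 complement genes 4 were called, and 4 when adjusted over the list alone (mean 0.45, camera adjusted p = 1.02e-05; adjusted p = 0.0429 with an estimated correlation). Among 20 neuropeptide genes 3 rose, Kiss1 by 1.62 ± 0.39, Tac2 by 0.80 ± 0.21 and Avp by 0.74 ± 0.20 (camera adjusted p = 0.00105; adjusted p = 0.331 with an estimated correlation). Ribosomal protein genes rose in 12 of 24 cases and 20 when adjusted over the list alone (camera adjusted p = 1.54e-13; adjusted p = 0.141 with an estimated correlation). Prl, the pituitary hormone prolactin, rose by 3.98 ± 1.01 (adjusted p = 0.0274), Gfap, an astrocyte filament, by 0.79 ± 0.22, and Hba-a1 by 1.89 ± 0.38. The clock gene Per2 fell by 0.53 (SE 0.15) and Zbed5 by 1.77 (SE 0.50). The split was 905 higher and 787 lower under median-of-ratios scaling and 627 and 531 under quantile normalization. The count was 188 without 18-month CON replicate 2 (125 higher, 63 lower) and 3983 without 8-week CON replicate 5 (1111 higher, 2872 lower). The balance turned in 7 of 19 fits without 1 library.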

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

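The tests of immune cells, scaling and sex for the interferon genes and the tests of clock phase and of the clock arms, as given here, were chosen after the results were seen. So were the interferon score, clock index, number and closest library of the colon library. The position of the colon library was planned before.

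The first pattern is a colon library labelled 18-month CON replicate 5, with Ddx3y at 11.3 FPKM where the nearest other library of its group had 0.01. Genes called for age without it were taken, leaving out sex chromosomes, interferon genes and genes with a CRD effect differing by age. Over these 30 genes its median position from the other 18-month CON libraries (0) to the 8-week CON libraries (1) was 0.697. The other 4 libraries, scored the same way, had -0.231 to 0.334. Each of these rests on only 7 to 9 genes, from fits that kept the library with Y-linked transcripts. Over the 170 genes kept when the last 2 kinds stay in, the position of that library was 0.352, against -0.248 to 0.215 for the other 4. Its interferon score of 4.91 lies within the other 18-month CON libraries (4.26 to 4.99) and below the 9 colon libraries at 8 weeks (5.64 to 6.85). The score goes against a library of an 8-week-old animal under this label and the position of 0.697 goes with it, while an 18-month-old male may give that position too, since genes called for age may differ by sex. Number 5 of 18-month CON occurred in the colon alone, and colon 8-week CON alone among 8-week groups lacked a number (1). This library's clock index was -0.20, against 1.08 to 1.71 in the other 18-month CON and -0.25 to 0.79 in 8-week CON colon libraries. These go with an 8-week-old animal. The colon library closest to it was 18-month CRD replicate 1 (r = 0.989), which goes against one. An 8-week-old animal and an 18-month-old male cannot be told apart here. Without this library the colon had 48 calls for CRD at 18 months, 3 at 8 weeks, 56 for the difference and 178 for age.

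The second pattern is that interferon genes were higher under CRD at 18 months and lower at 8 weeks in the 4 solid tissues. With another scaling 16 of 16 fits kept the direction at a camera adjusted p under 0.05 (preset correlation). Camera sets the list against the other genes, and a scaling moves most genes of a library alike, so these fits could hardly fail. They do not decide about the authors' scaling. The median change of all genes lay between -0.10 and 0.06 in the 8 comparisons. A shift of all genes by that much is too small to give the list means (0.52 or more in size). With an estimated correlation and the authors' scaling, 7 of the 8 comparisons had camera adjusted p = 0.154 to 0.706 and the colon at 18 months 0.0384. Immune cells in the tissue stay open, with marker means of the sign of the interferon change in 0 of 4 comparisons in the cecum and colon and 3 of 4 in the hippocampus and hypothalamus, and adjusted exact permutation p-values of 0.254 to 0.778. These markers left out neutrophils, whose list rose by 1.45 with the interferon genes in the colon at 18 months. Sex or processing batch in place of age cannot be told apart from age, since 1 library of the 18-month tissues had Y-linked transcripts and batches were not given in the sources used here, and age itself stays open as well.

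The third pattern is a wide spread of clock genes between 8-week CRD libraries: Ciart in cecum replicate 4 was at 8.14 FPKM (nearest other 1.92) and Dbp in colon replicate 4 at 61.6 (nearest other 20.2). Numbers explained 66.0% of the variance of the clock index in this group (exact permutation p = 8.10e-06, adjusted p = 3.24e-05), with replicate 4 highest in 4 and replicate 5 lowest in 3 of 4 tissues, against 47.9% in 18-month CRD (adjusted p = 0.0494), 43.7% in 8-week CON (0.126) and 1.19% in 18-month CON (0.999). With unrelated numbers such a share is on average the inverse of the number of tissues. Tissues were not scaled, so the share in 8-week CRD rests mostly on the cecum and colon. The SD of the index was 0.93 and 1.06 there, against 0.25 and 0.14 in the hippocampus and hypothalamus. By the permutation test, the clock phase of single animals may differ within 8-week CRD, if same numbers mean the same animal, which the labels do not state. Tissue content of single libraries stays open: the r of the output arm with the Arntl arm was -0.817 (permutation p = 0.0544, 10 animals), and -0.597 without the 2 farthest animals (permutation p = 0.0363). The SD of the index over animals was 0.58 in CRD and 0.19 in CON at 8 weeks (exact permutation p = 0.238), and 0.30 and 0.02 at 18 months (exact permutation p = 0.0286).

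Other single libraries stood apart from their group, and 19 such values were found in the 152 groups of values examined. For independent normal values chance gives about 1 in 20, or 7.6. FPKM are skewed and several of the values come from the same library, so 19 cannot be weighed against 7.6. H2-Aa was at 220.5 FPKM in colon 18-month CRD replicate 4 (nearest other 141.6). In hippocampus 18-month CRD replicate 2, Ifi27l2a was at 106.9 (nearest other 53.0), Rtp4 at 35.2 (10.5) and the interferon score at 5.09 (3.21). In hypothalamus 18-month CRD replicate 2, Rtp4 was at 40.3 (13.6) and the score at 5.04 (3.48). The score of cecum 18-month CON replicate 3 was 5.81 (4.62). In the hypothalamus Dbp was at 68.6 in 8-week CON replicate 2 (84.7), Clec7a at 0.98 in 8-week CON replicate 1 (0.44) and at 0.32 in 8-week CRD replicate 1 (0.21). Prl was at 144.4 in 18-month CON replicate 4 (26.4), 31.4 in 18-month CRD replicate 1 (8.82) and 204.9 in 8-week CRD replicate 1 (7.90), which also had Pomc at 1737 (88.0). Hippocampus 8-week CRD replicate 2 had a sum of 572255 FPKM (458956) and a mean correlation within its group of 0.954 (0.973).

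By the test of the difference, CRD effects differed between ages (18 months minus 8 weeks) for the genes below, all that were called except in the colon. In the cecum these were Ifi27l2a 3.68, Bst2 2.50, Ifitm3 2.18, H2-Q10 1.67 and Trp53inp1 -1.21. In the colon 52 were called, and the 14 named in the results are given here: Ifi27l2a 4.01, Ifit3 2.73, Oas2 2.72, Isg15 2.47, Ifit3b 2.44, Xaf1 1.71, Oas1a 1.29, Cd3d -1.73, H2-DMb1 -2.07, H2-DMa -2.11, H2-Aa -2.33, Cd74 -2.55, Cd7 -3.03 and Ccl5 -3.55. In the hippocampus they were Ifi27l2a 4.01, Rtp4 2.91 and Epsti1 0.91, and in the hypothalamus Ifi27l2a 3.34, Rtp4 2.69, Bst2 2.43, Lgals3bp 2.39, Ifi27 2.15, Irf9 1.76 and Slfn2 1.46.

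Of the 14 clock genes whose CRD effects differed between tissues at 18 months, 12 are given with their adjusted p-values by limma's F test: Dbp 5.11e-07, Cry1 2.06e-06, Nr1d1 and Ciart 5.47e-05, Nr1d2 0.000274, Tef 0.000923, Arntl and Hlf 0.00321, Npas2 0.0119, Nfil3 0.0131, Csnk1e 0.0197 and Bhlhe41 0.0353.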

How the results depend on the processing

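The fits without low-Ttr hippocampus libraries, the PBMC fit without globins and the tests between tissues with the number as the animal were chosen after results were seen. The causes of the changes in count below were not tested. With a pseudocount of 0.1 the hypothalamus difference between ages had 14 calls. With no filter on low values the cecum difference had 0, the hypothalamus CRD effect at 18 months 0, its difference 3 and its age effect 925, and PBMC 0. With a mean of at least 2 FPKM the cecum CRD effect at 8 weeks had 3, the colon one at 8 weeks 1 and the hippocampus age effect 36.

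Median-of-ratios scaling gave 2 calls for the cecum CRD effect at 18 months, 7 for the colon at 8 weeks, 4 for the hypothalamus difference and 0 for PBMC. Quantile normalization gave 3 for the cecum difference, 4 for the colon at 8 weeks, 0 for the hippocampus difference, 145 for the hippocampus age effect (109 higher, 36 lower) and 14 for PBMC. The 2 compared groups fitted alone gave 8, 3 and 88 calls in the cecum (CRD at 18 months, CRD at 8 weeks, age), 23 and 72 in the colon (CRD at 18 months, age), 1 and 1618 (533 higher, 1085 lower) in the hippocampus (CRD at 18 months, age), and 0 for CRD in the hypothalamus at 18 months. Without the low-Ttr hippocampus libraries there were 1 call for CRD at 18 months, 0 for the difference and 997 for age (381 higher, 616 lower). PBMC without globins had 87 calls (79 higher, 8 lower), and the clock genes that differed between tissues numbered 15 at 18 months and 0 at 8 weeks by limma with the number as the animal.

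The fit with the replicate number as a block gave 0, 0, 1 and 21 calls in the cecum (CRD at 18 months, CRD at 8 weeks, difference, age), 1, 17 and 0 in the colon (CRD at 18 months, difference, age), 1 and 616 (175 higher, 441 lower) in the hippocampus (difference, age), and 0, 4 and 3483 in the hypothalamus (CRD at 18 months, difference, age). Same-numbered CON and CRD libraries did not correlate throughout in solid tissues. Per age and tissue their lowest correlation was between -0.34 and 0.0163 and their highest between 0.10 and 0.533. In the cecum at 8 weeks number 5 had 0.533 (mean -0.197 with other numbers) and number 2 had -0.34 (0.108). In the colon at 8 weeks each was above 0 (0.0163 to 0.311). Pairing by number therefore stays open. In PBMC, where 2 libraries per schedule force the 2 pairs to share 1 value, the correlation was 0.528, and the fit with the block gave 180 calls (153 higher, 27 lower).

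With 1 library left out at a time, the cecum counts ran from 2 to 12 (CRD at 18 months), 1 to 2 (CRD at 8 weeks), 0 to 84 (difference) and 26 to 315 (age). Those of the colon ran from 22 to 468, 0 to 7, 46 to 64 and 71 to 255. Those of the hippocampus ran from 0 to 0, 0 to 0, 0 to 9 and 25 to 284, those of the hypothalamus from 0 to 18, 0 to 2, 3 to 22 and 188 to 3983, and PBMC from 7 to 5261, with the lone library of a schedule assumed to vary like the 2 of the other. The correlation of CRD effects between ages ran from -0.355 to -0.0546 in the cecum, -0.164 to 0.197 in the colon, 0.274 to 0.611 in the hippocampus and -0.225 to 0.151 in the hypothalamus.

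For some lists the direction against the other genes, as camera takes it, reversed, and the list means in those fits are given here. Under quantile normalization these were oxidative phosphorylation in the cecum (-0.0339 for CRD at 18 months, -0.0116 for the difference, 0.0299 for age), the hippocampus (-0.0130 for age) and the hypothalamus (-0.00415 for CRD at 18 months, -0.0299 for age), ribosomal proteins in the hippocampus (0.0117 for CRD at 8 weeks, 0.00926 for the difference) and neuronal genes in the hypothalamus (-0.0108 for age). With 1 library left out these were smooth muscle in the colon difference (from -0.278 without 18-month CRD replicate 5 to 0.560), ribosomal proteins in the hippocampus difference (from -0.177 to 0.0850 without 8-week CRD replicate 2), and 5 lists in the hypothalamus at 8 weeks. These were striatum (from -0.136 to 0.0411 without CON replicate 2), oligodendrocytes (from -0.151 to 0.0246 without CON replicate 3), astrocytes (from -0.133 to 0.000273 without CON replicate 5), heat shock (from -0.0255 to 0.194) and endoplasmic reticulum stress (from 0.000622 to 0.105), the last 2 without CRD replicate 1 at their low end.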

Other observations

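The tests of same-numbered libraries and the reading of gut transcripts in the brain were chosen after results were seen, as were the bounds for the splits. Heat shock genes, whose products refold proteins, fell with age in CON by 0.75 on average in the cecum (camera adjusted p = 1.21e-09; adjusted p = 0.436 with an estimated correlation) and by 0.72 in the colon (camera adjusted p = 4.74e-10; adjusted p = 0.318 with an estimated correlation). Of 13 members limma called 0 over all genes in each tissue, and 6 and 7 were lower when adjusted over the list alone. The pituitary list passed camera in the hypothalamus at 8 weeks under CRD, with a mean of 1.20 (camera adjusted p = 0.000643; adjusted p = 0.154 with an estimated correlation). Of its 5 members limma called 0 over all genes and 0 when adjusted over the list alone. Without CRD replicate 1 its mean was 0.59 and it did not pass (camera adjusted p = 0.0946). That library also had 1737 FPKM of Pomc, a pituitary transcript outside the tested list, against 25.3 to 88.0 in the other 4.

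The interferon scores of same-numbered libraries went together in the hippocampus and hypothalamus within groups (r = 0.865, permutation p = 0.00175, adjusted p = 0.0105 over 6 pairs of tissues, 19 pairs of libraries). Without the 2 farthest pairs r was 0.722 (permutation p = 0.0175). In the cecum and colon r was -0.416 (permutation p = 0.190, 17 pairs of libraries) and -0.0848 without the 2 farthest. The same animal in the hippocampus and hypothalamus is consistent with r = 0.865, and for the cecum and colon it stays open at -0.416.

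Lypd8, a transcript of the gut epithelium, was at 1 FPKM or more in 9 of 9 hypothalamus libraries at 18 months (1.33 to 5.39), in 5 of 9 hippocampus libraries at 18 months (0.06 to 4.79) and in 0 of 20 brain libraries at 8 weeks (0.18 or less). In PBMC, all at 18 months, Lypd8 was at 0.13 and 2.3 FPKM in CON and at 1.75 and 3.53 in CRD. Gut libraries held 5331 to 19916 FPKM of it. The source of these transcripts outside the gut was not tested.

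Other splits of the samples into groups of the same sizes were fitted, 35 for the cecum CRD effect at 18 months and 100 for each other comparison, the real one included. A comparison is said here to pass where under 5% of the splits had as many calls as the real one. That share was not adjusted over the comparisons and does not exclude chance. It does not speak for how firm the calls are: without 1 library they were lost in 7 of 18 fits (cecum difference), 1 of 18 (colon CRD at 8 weeks), 15 of 19 (hippocampus difference) and 5 of 19 (hypothalamus CRD at 18 months). In the cecum CRD at 18 months passed (4 calls, 1 split with as many, highest other 0). So did the difference (5 calls, 1 split, highest other 0) and age (207 calls, 2 splits, highest other 209). CRD at 8 weeks did not (1 call, 6 splits, highest other 2639). In the colon CRD at 18 months (76 calls, 1 split, highest other 1) and at 8 weeks (2 calls, 1 split, highest other 1) passed. So did the difference (52 calls, 3 splits, highest other 1121) and age (138 calls, 1 split, highest other 84). For age the real split also separates libraries by Y-linked transcripts, apart from 1 colon library, so it cannot tell age from sex.

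In the hippocampus limma called 0 genes for CRD at 18 months (749 at an unadjusted p under 0.05, highest other split 294) and at 8 weeks (2948, highest other split 6), so all 100 splits had as many and say nothing about chance. There age (67 calls, 1 split, highest other 5) and the difference (3 calls, 4 splits, highest other 541) passed. In the hypothalamus CRD at 18 months (4 calls, 1 split, highest other 1) passed. So did the difference (7 calls, 2 splits, highest other 481) and age (1436 calls, 3 splits, highest other 4265). At 8 weeks limma called 0 in the hypothalamus (203 at an unadjusted p under 0.05, highest other split 175), so its 100 splits say nothing about chance either. Splits with several times the real calls (2639, 1121, 541, 481 and 4265) point to a structure of the samples, which was not examined.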
